A study of Homo sapiens with 12 samples.

How the data were processed

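Gene expression was measured on 12 Illumina HumanHT-12 V4.0 beadchips, each hybridised with biotin-labelled RNA amplified from MDA-MB-231 cells transfected with 100 nM siRNA. Per the labels, 9 arrays held cells given an ARF1 siRNA pool and 3 held cells given a scramble siRNA. The source names split the 9 arrays into ARF-1, ARF-2 and ARF-4, with 3 arrays in each. Arrays were assigned to groups from these labels alone.

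The deposited files give, for each probe and array, the bead summary signal (intensity, linear scale, not normalized) and a detection p-value against the negative control beads, exported with BeadStudio 2.3.47 per the submitters' processing notes. A deposited table of processed values is also on an intensity scale. Its columns equal the quantile normalization of the deposited signals, with a largest log2 difference of 6.06e-07 and all 12 columns matching their own array, so it carries no background correction. The files list 47323 probes, of which 12 have empty values and were left out. The other 47311 were used. Of all 47323 listed probes, 30113 carried 1 gene symbol, 8 several and 17202 no listed gene. No genome build was used, and probes are named by gene symbol and probe identifier only.

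Signals were corrected for background and normalized with neqc in limma 3.58.1 under R 4.3.3. This function fits a normal-exponential background model from the detection p-values, adds an offset of 16, quantile normalizes the arrays and takes log2. A probe was kept when its detection p-value was below 0.05 on at least 3 of the 12 arrays. This left 22195 probes, 16192 of them with 1 symbol, for 12048 genes. Each gene was represented by its kept probe with the highest mean value over all 12 arrays; 3249 genes had more than 1 kept probe. Where all arrays of 1 group left a gene undetected, its fold was given as a bound, computed against the detection limit of those arrays.

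The comparison of the 9 arrays with the 3 scramble arrays used limma with 2 condition means, so that the spread between the 3 sets counted as error. Each set was also compared with scramble, and with the other sets, as contrasts of 4 group means with 1 shared estimate of the spread. A moderated F-test asked whether the 3 sets differed. Tests were two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05 on the adjusted p. A second count required a fold of at least 1.5. ARF1 was also tested by an exact permutation test over every split of the arrays into 9 and 3. A gene was called separated when all arrays of 1 group lay on 1 side of all arrays of the other.

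Gene groups came from 31 lists: the ARF family, the COPI and COPII coats, stress and secretory pathways, epithelial and mesenchymal markers, adhesion, lipid, cell cycle, cytokine, interferon, lysosome, apoptosis and energy pathways, ribosomal proteins, histones, small RNA machinery, and markers of luminal, basal, leukocyte, and endothelial or adipocyte cells. Of 916 list members, 850 matched a probe named for the gene, and 737 distinct symbols were kept. Lists were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 31 lists. The same test with a correlation estimated from the data, and fry, which asks whether the members of a list move one way on balance or (mixed) in either direction, were alternatives. Lists of ribosome biogenesis genes and of structural RNAs were added after the data were seen and were adjusted apart from the others.

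The lists, tests, threshold, alternatives and the rule for naming genes were fixed before the data were examined, except where the text says otherwise. The rule named ARF1, ARF3, ARF4, ARF5, ARF6 and 8 genes of the epithelial-mesenchymal transition. It then named the 10 largest rises and 10 largest falls among the separated genes past the threshold on the 9 arrays, and the 4 largest each way in each set. It also took the 6 genes with the widest range among the 3 sets past the F-test, and up to 4 members of each list with the smallest adjusted p, from which the text takes examples.

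Alternatives covered background correction (none, or normexp with an offset of 50), normalization (median scaling, cyclic loess, the authors' value table), the probe filter (none, or detection p below 0.01 on all arrays), array weights, a trended and robust variance prior, a block for the replicate number, 4 group means or the source name as a random block (statmod 1.5.0), other set tests, the mean of all probes of a gene, other ARF1 probes, fits on only the 6 arrays compared, and leaving out each array in turn. Fits without the ARF-4 arrays and with array brightness as a covariate were added after the data were seen. Other splits of the arrays were refitted, at most 100 per result.

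The procedure was tested on simulated data with 22195 probes, of which 200 were changed. With 9 arrays against 3, it recovered 76.1% of 1.5-fold changes, 88.1% of 2-fold changes and 98.5% of 4-fold changes, and called 8 of 21995 unchanged probes. For ARF-1 against scramble, 3 arrays each, these shares were 34.3%, 82.1% and 100%, with 3 unchanged probes called. For ARF-4 against ARF-1 they were 44.8%, 79.1% and 98.5%, with 9 unchanged probes called. Among the 31 lists, 0 were called without a change, and a list raised by 0.3 on the log2 scale was called. The simulated probes were drawn independently of each other, with the spread within sets and no spread between sets. The list result therefore does not cover lists whose genes move together. The shares recovered with 9 arrays hold only where the sets do not differ. Comparisons that share the 3 scramble arrays were set beside 100 simulations of unchanged groups that share them. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

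Mean raw signal per array ranged from 303 to 518, and 39.1% to 42.8% of probes were detected. The number of arrays limits the precision of every value.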

Results

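Gene expression was profiled in MDA-MB-231, a human triple-negative breast cancer cell line of mesenchymal appearance, after transfection with small interfering RNA (siRNA). Per the labels, 9 arrays held cells given siRNA against ARF1, a small GTPase that recruits the COPI vesicle coat to Golgi membranes, and 3 arrays held cells given a scramble siRNA. The source names divide the 9 arrays into sets called ARF-1, ARF-2 and ARF-4, with 3 arrays each, and the labels do not say what the numbers stand for. Here the hyphen tells the sets from the genes ARF1 and ARF4. The series set out to study ARF1 in the epithelial-mesenchymal transition (EMT), in which epithelial cells lose cell-cell adhesion and gain motility. Mean raw signal per array ranged from 303 to 518, and between 39.1% and 42.8% of the 47311 probes with values were detected on an array. Differences below are on the log2 scale with their standard error (SE), from 22195 probes of 12048 genes. The labels do not say whether the replicates of a set were separate cultures, so each p-value measures only the spread between these samples, which may be technical.

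No ARF1 probe was lower past the threshold on the arrays labelled ARF1 siRNA. Its brightest probe (ILMN_1802203) read 11.78 ± 0.07 (SD, n = 9) there and 11.64 ± 0.06 (SD, n = 3) on the scramble arrays, a difference of 0.14 ± 0.08 (SE; adjusted p = 0.321). The 95% confidence interval of that difference, -0.04 to 0.32, allowed a fall of at most 2.90% for this probe under the normalization used. Median scaling reduced the difference to 0.02 (adjusted p = 0.970). An exact two-sided permutation test over all 220 splits of the 12 arrays gave p = 0.0136, with the higher signal on the arrays labelled ARF1 siRNA. After Benjamini-Hochberg adjustment over the 3 ARF1 probes it was 0.0409. That test exchanges single arrays, although they come in sets of 3 that may be technical replicates. Whole sets can be exchanged in too few ways for a small p, so a rise of ARF1 is not shown. The difference was 0.08 in ARF-1 (adjusted p = 0.554), 0.21 in ARF-2 (adjusted p = 0.0758) and 0.12 in ARF-4 (adjusted p = 0.416). A second probe (ILMN_2330948) differed by 0.16 ± 0.11 (adjusted p = 0.399), and the dimmest (ILMN_1661458), detected on 8 arrays, by -0.18 ± 0.14 (adjusted p = 0.453). Their intervals allowed falls of up to 5.6% and 28.4% in normalized signal. For the dimmest probe this is no limit on a fall of the transcript. It averaged only 5.11 on the scramble arrays, and the offset added before taking log2 shrinks the changes of such dim probes. In ARF-1 alone the interval of its difference reached -0.63. Because a fall of the targeted transcript was not shown, the groups are named by their labels throughout, and no difference below is shown to follow from loss of ARF1.

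**Figure D1:**
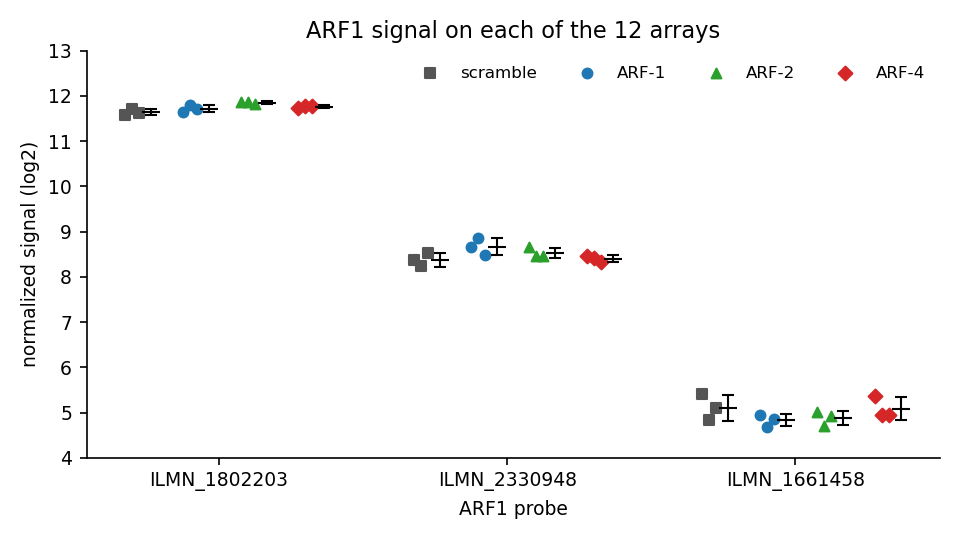
Normalized signal (log2, vertical axis) of the 3 ARF1 probes (horizontal axis) on each of the 12 arrays, coloured by source name; black bars give the mean ± SD of each set of 3. The brightest probe averaged 11.64 on the scramble arrays and 11.78 on the arrays labelled ARF1 siRNA.

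The 12 arrays did not divide simply into scramble and ARF1 siRNA. The first principal component, with 39.4% of the variance, placed the ARF-1 and ARF-2 arrays at 22.4 to 24.8, the scramble arrays at -29.9 to -27.8, and the ARF-4 arrays at -19.4 to -18.0. The second component, with 14%, parted ARF-4 (-23.7 to -21.1) from scramble (16.4 to 18.6). Arrays of ARF-1 and ARF-2 correlated with each other across probes at 0.990 to 0.993, as arrays within a set did (0.991 to 0.993); probes are not independent replicates.

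**Figure D2:**
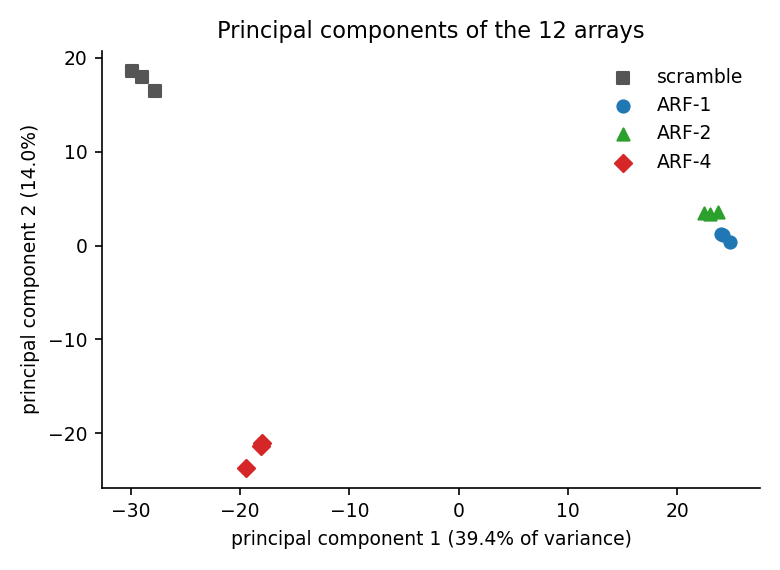
Each point is 1 of the 12 arrays, at its value on the first principal component (horizontal, 39.4% of variance) and the second (vertical, 14%), coloured by source name. The ARF-1 and ARF-2 arrays lie together at 22.4 to 24.8 on the first component, and the ARF-4 arrays lie apart from them and from the scramble arrays.

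The arrays labelled ARF1 siRNA were compared with scramble to find the transcripts that went with the treatment. IL24, a cytokine of the interleukin-10 family, rose by 2.29 ± 0.18 (4.91-fold; adjusted p = 7.8e-06) from 5.71 ± 0.20 (SD, n = 3). IL11, of the interleukin-6 family, rose by 2.03 ± 0.13 (adjusted p = 8.3e-07), and the growth factor midkine (MDK) by 1.80 ± 0.16 (adjusted p = 1.9e-05), while 2 other MDK probes read 0.05 (adjusted p = 0.903) and -0.12 (adjusted p = 0.680). The monocyte attractant CCL2 moved the other way. It was undetected on all 9 arrays labelled ARF1 siRNA, at least 3.40-fold lower than the 6.68 ± 0.14 (SD, n = 3) of scramble (adjusted p = 2.1e-08).

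Other large rises were the small nucleolar RNA SNORD13, by 2.57 ± 0.20 (5.94-fold), the actin-associated PDLIM7 by 1.73 ± 0.14, ALOX5AP, which serves leukotriene synthesis, by 1.58 ± 0.10, and PHGDH, the first enzyme of serine synthesis, by 1.44 ± 0.15. The cancer-testis gene MAGEB2 was at least 3.73-fold higher, and NNMT, which methylates nicotinamide, and ZNF467 at least 3.00-fold higher, since no scramble array detected them. The largest falls after CCL2 were AGR2, a disulfide isomerase of the endoplasmic reticulum, by -1.64 ± 0.31, the long non-coding RNA UCA1 by -1.49 ± 0.31, the trypsin PRSS3 by -1.43 ± 0.23, COX7B2 by -1.41 ± 0.13 and ID3, an inhibitor of helix-loop-helix transcription factors, by -1.39 ± 0.31. The transcription factor FOXQ1 fell by 1.33 ± 0.15, the NF-kB subunit RELB by 1.30 ± 0.15, TRIML2 by 1.29 ± 0.15 and PAGE5 by 1.27 ± 0.24. Adjusted p for these 16 genes ranged from 8.3e-07 (ALOX5AP) to 0.0146 (ZNF467), and all 9 arrays lay on 1 side of all 3 scramble arrays for each. Other probes of PDLIM7 read 0.30 (adjusted p = 0.202) and 0.05 (adjusted p = 0.864), and a second AGR2 probe read -0.30 (adjusted p = 0.118). ZNF467 lost the threshold without scramble replicate 1, 2 or 3 (adjusted p = 0.0554, 0.0691 and 0.0685), ID3 without replicate 2 or 3 (0.0563 and 0.0577) and UCA1 without replicate 1 (0.0501). MAGEB2, PAGE5 and PRSS3 have close relatives that a probe might also bind.

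Of the 22195 probes, 2423 passed the threshold, 1247 higher and 1176 lower, for 1505 genes (783 higher, 722 lower). Among all 12048 genes, called or not, the 9 arrays and the 3 scramble arrays did not overlap in 1779 (14.8%), where chance alone gives 0.909% if arrays are independent. With a fold of at least 1.5, 998 probes remained (571 higher, 427 lower). The counts rested on the scramble arrays and on how the 3 sets were modelled: 974, 844 or 865 probes passed without scramble replicate 1, 2 or 3, 551 with the source name as a random block, 5267 with 4 group means, 5638 with array weights and 6478 without the ARF-4 arrays. Under median scaling 30.4% of the called probes were higher, against 51.5% here, and without background correction dim genes changed less (CCL2 -0.88, IL24 1.30, MAGEB2 0.83, NNMT 0.72, ZNF467 0.72, ALOX5AP 0.69, MDK 1.21, UCA1 -0.85, PAGE5 -0.59).

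**Figure D3:**
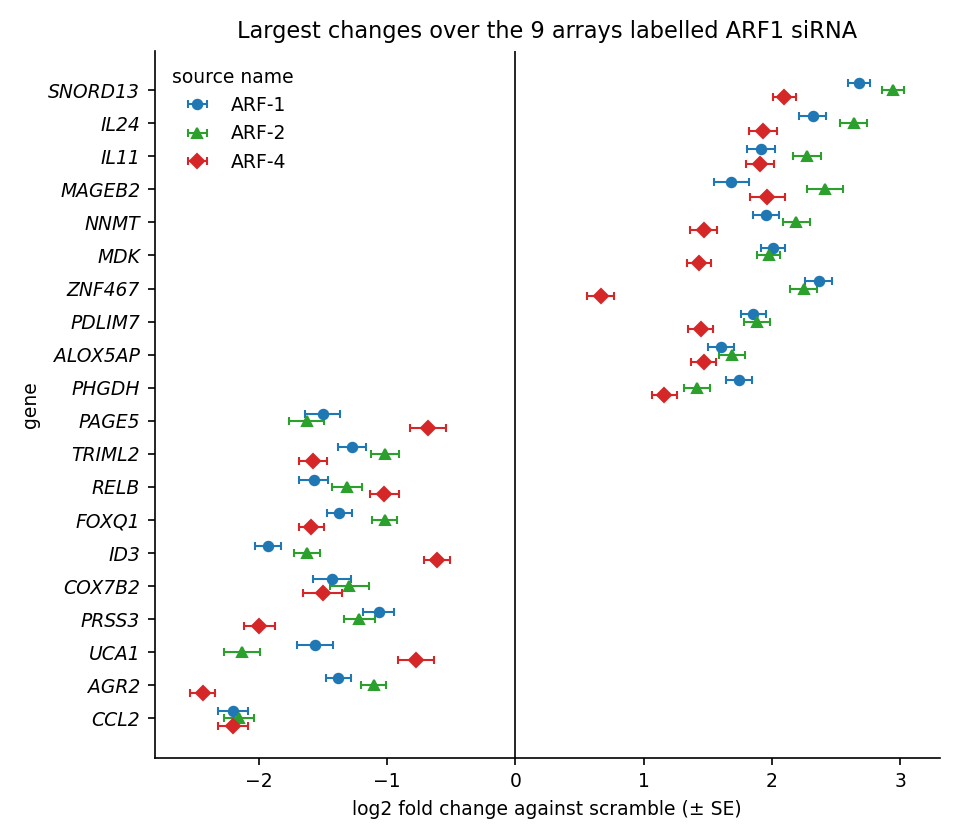
Log2 fold change against scramble (horizontal axis; bars, SE) of the 10 largest rises and 10 largest falls over the 9 arrays, drawn for each set of 3 arrays against 3 scramble arrays. IL24 rose by 2.32 in ARF-1 and 1.93 in ARF-4; the points of CCL2, MAGEB2, NNMT and ZNF467, undetected on all arrays of 1 condition, depend on the background correction and are no exact folds.

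Among EMT genes, the transcription factor SNAI2 (Slug) fell by 1.14 ± 0.27 (adjusted p = 0.0152), and its second probe read -0.69 (adjusted p = 0.0305). This call was lost without any 1 scramble array (adjusted p = 0.0561, 0.0784 and 0.0652 without replicate 1, 2 and 3). By set, SNAI2 fell by 1.32 in ARF-1 and 1.54 in ARF-2, and read -0.54 in ARF-4 (adjusted p = 0.105); the sets differed (F-test adjusted p = 0.00612). ZEB1 read -0.41 ± 0.16 (adjusted p = 0.12; -0.56, -0.41 and -0.25 in ARF-1, ARF-2 and ARF-4, F-test adjusted p = 0.496) and the intermediate filament gene VIM -0.14 ± 0.08 (adjusted p = 0.320). FN1 was detected on 3 arrays, none of them scramble, and did not pass (adjusted p = 0.395), so no fold is given. CDH1, SNAI1 and TWIST1 were detected on 0 arrays and CDH2 on 1, so they were not tested. Of 18 epithelial genes 1 rose and 2 fell (2 and 4 adjusted over the list alone): EPCAM rose by 0.51 ± 0.12, and KRT7 and the membrane protein MAL2 fell by 0.65 ± 0.14 and 0.70 ± 0.10. The list as a whole was not called (adjusted p = 0.515). Of 26 mesenchymal genes 2 rose and 5 fell (3 and 6 adjusted over the list alone; list adjusted p = 0.515). TAGLN, an actin-binding smooth muscle protein, rose by 1.10 ± 0.12 and tenascin C (TNC) by 0.66 ± 0.11, while cadherin 11 (CDH11) fell by 1.09 ± 0.17 and COL6A1 by 0.96 ± 0.21. Integrin and focal adhesion genes numbered 31, of which 2 rose and 5 fell (adjusted p = 0.515): ZYX rose by 0.52 ± 0.10, CAV1 fell by 0.46 ± 0.10 and LAMB3 by 0.49 ± 0.11. Of 23 YAP and TAZ targets 2 rose and 3 fell (adjusted p = 0.515). Several of these gene calls were lost without 1 scramble array: EPCAM (adjusted p = 0.0658 and 0.0825) and KRT7 (0.0567 and 0.0636) without replicate 1 or 3, COL6A1 (0.0593 and 0.0598) and CAV1 (0.0532 and 0.0524) without 1 or 2, and LAMB3 (0.0517 and 0.103) without 1 or 3. Median scaling lost EPCAM (0.181), TNC (0.0671) and ZYX (0.146), and other probes of EPCAM (0.0875 and 0.364) and ZYX (0.0674) did not pass.

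Among relatives of ARF1, ARF3 read -0.21 ± 0.14 (adjusted p = 0.343), ARF4 0.20 ± 0.10 (adjusted p = 0.195), ARF5 0.14 ± 0.12 (adjusted p = 0.501) and ARF6 0.03 ± 0.13 (adjusted p = 0.905). Against scramble, ARF4 read 0.31 in ARF-1 (adjusted p = 0.0288), 0.12 in ARF-2 and 0.17 in ARF-4, and the sets were not shown to differ (F-test adjusted p = 0.314). ARF5 read 0.29 in ARF-1 (adjusted p = 0.0402), 0.20 in ARF-2 and -0.08 in ARF-4, and ARF-4 differed from ARF-1 (adjusted p = 0.0153). In the list of 24 ARF family members and regulators 1 rose and 2 fell (adjusted p = 0.624): the GTPase-activating GIT2 rose by 0.69 ± 0.17, its paralog GIT1 fell by 0.53 ± 0.13 and the exchange factor CYTH2 by 0.38 ± 0.10. Of 28 COPI and Golgi genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.191). They included the Golgi tether GOLGB1, up by 0.43 ± 0.09, and KDELR3, a receptor that returns proteins to the endoplasmic reticulum, up by 0.84 ± 0.19. The COPII list had 0 rises and 1 fall among 18 genes (adjusted p = 0.529). In the unfolded protein response list 4 of 21 genes rose and 1 fell (adjusted p = 0.591). The chaperones HSP90B1 and PDIA6 rose by 0.72 ± 0.16 and 0.58 ± 0.11, and the chaperone HYOU1 fell by 0.98 ± 0.14. Calls lost without 1 scramble array were GIT2 (adjusted p = 0.0957 and 0.102 without replicate 1 and 3), GIT1 (0.116 and 0.0703 without 2 and 3), CYTH2 (0.107, 0.0976 and 0.0675 without 1, 2 and 3), GOLGB1 (0.0809 without 3), KDELR3 (0.0691 and 0.0685 without 2 and 3) and HSP90B1 (0.0565 and 0.0613 without 1 and 2). Median scaling lost CYTH2 (0.0635), GOLGB1 (0.303) and PDIA6 (0.107), and other probes of GIT2 (0.198) and CYTH2 (0.174 and 0.554) did not pass.

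Genes activated by ATF4, the transcription factor of amino acid and translation stress, were higher as a group: 10 of 28 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.32 (adjusted p = 1.2e-04, but adjusted p = 0.612 with an estimated correlation). Beside PHGDH, the alanyl-tRNA synthetase AARS1 rose by 0.67 ± 0.10 and the serine synthesis enzyme PSAT1 by 0.62 ± 0.13, while PPP1R15A, which reverses the translation block, fell by 0.37 ± 0.08. Genes of G2 and mitosis were lower as a group: 11 of 42 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -0.22 (adjusted p = 1.8e-05, but adjusted p = 0.302 with an estimated correlation). The phosphatase CDC25B fell by 0.64 ± 0.13, the proliferation marker MKI67 by 0.73 ± 0.16, topoisomerase TOP2A by 0.48 ± 0.10 and survivin (BIRC5) by 0.51 ± 0.12. By fry, both lists moved one way (adjusted p = 0.01 and 6.5e-04). E2F and S phase genes had 1 rise and 3 falls among 42 (adjusted p = 0.198), and G1 regulators 2 rises and 2 falls among 24 (adjusted p = 0.599), with cyclin D1 (CCND1) and KLF4 down by 0.74 ± 0.13 and 0.82 ± 0.17 and CCND2 up by 0.69 ± 0.14. Without 1 scramble array the calls of BIRC5 (adjusted p = 0.0718, 0.0597 and 0.0679 without replicate 1, 2 and 3), PPP1R15A (0.0552 and 0.0578 without 1 and 2), KLF4 (0.0546 without 1), and PSAT1 (0.0665), CDC25B (0.0533), MKI67 (0.0636), TOP2A (0.0574) and CCND2 (0.0507) without 2 were lost. Median scaling lost PSAT1 (0.0885) and PPP1R15A (0.0578), and other probes of BIRC5 (0.0766) and CCND2 (0.757) did not pass.

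The other 29 lists were not called over the 9 arrays. Of 34 interferon-stimulated genes 1 rose and 7 fell (adjusted p = 0.515): MX1 rose by 0.83 ± 0.11, while OAS3 fell by 1.02 ± 0.18, IFIH1 by 0.53 ± 0.10 and SAMD9L by 0.59 ± 0.12. The NF-kB and cytokine list, which holds IL24, IL11, CCL2 and RELB, had 5 rises and 5 falls among 29 genes (adjusted p = 0.875); its median was -0.02 and its mean 0.13. Immediate early genes had 3 rises and 2 falls among 27 (adjusted p = 0.515). Lysosome and autophagy genes had 4 rises and 2 falls among 29 (adjusted p = 0.475), with the autophagy genes GABARAPL1 and WIPI1 up by 1.26 ± 0.24 and 0.94 ± 0.18 and the protease CTSD down by 0.57 ± 0.10. Sterol genes had 3 rises and 0 falls among 21 (adjusted p = 0.297), among them INSIG1, which holds back sterol synthesis, up by 0.92 ± 0.25 (adjusted p = 0.0297, and 0.0803 to 0.127 without 1 scramble array). Fatty acid genes had 1 rise and 2 falls among 26 (adjusted p = 0.57). Hypoxia and glycolysis genes had 0 rises and 3 falls among 32 (adjusted p = 0.515), including ADM, down by 0.48 ± 0.10, and the glucose carrier SLC2A1, down by 0.41 ± 0.11. The call of ADM was lost without scramble replicate 1 (adjusted p = 0.0577), and that of SLC2A1 without 1, 2 or 3 (0.0879, 0.0803 and 0.126) and under median scaling (0.0569). Oxidative phosphorylation genes had 2 rises and 0 falls among 38 (adjusted p = 0.191).

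In the p53 list 0 genes rose and 1 fell of 19 (adjusted p = 0.930), and among apoptosis regulators 2 rose and 2 fell of 25 (adjusted p = 0.769). The counts were 0 and 1 of 41 for ribosomal proteins (adjusted p = 0.529), 1 and 1 of 25 for heat shock and proteasome genes (adjusted p = 0.449), 3 and 1 of 22 for metallothioneins and NRF2 genes (adjusted p = 0.540), and 1 and 1 of 12 for the small RNA machinery (adjusted p = 0.515). Of 16 histone genes 3 rose and 2 fell (adjusted p = 0.669), with H2AJ up by 0.73 ± 0.10 and H2AC18 down by 1.01 ± 0.12. Markers of luminal, basal, leukocyte, and endothelial or adipocyte cells were not called as groups. Luminal breast markers had 1 rise and 2 falls among 14 (adjusted p = 0.515), the falls being AGR2 and SPDEF (-0.72 ± 0.12). Basal markers had 0 and 2 of 4 (adjusted p = 0.161), leukocyte markers 0 and 1 of 5 (adjusted p = 0.515), and endothelial and adipocyte markers 2 and 0 of 5 (adjusted p = 0.303), among them PPARG, up by 0.78 ± 0.16 (another probe, adjusted p = 0.0518).

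Adjusted over the list alone, rises and falls numbered 4 and 4 for G1 regulators, 1 and 8 for interferon-stimulated genes, 7 and 5 for NF-kB and cytokines, 5 and 2 for immediate early genes and 9 and 3 for lysosome and autophagy. They were 3 and 2 for fatty acid genes, 4 and 2 for apoptosis, 1 and 0 for oxidative phosphorylation, 0 and 0 for COPII and for ribosomal proteins, 4 and 1 for metallothioneins and NRF2 genes, 5 and 3 for histones, 0 and 3 for basal markers and 1 and 1 for leukocyte markers. The ARF family, unfolded protein response, integrin, YAP and TAZ, sterol, E2F, p53, hypoxia, heat shock, luminal, endothelial and small RNA lists kept their counts. The median and the mean differed in sign for the p53 list (0.11 and -0.01) and the histones (0.06 and -0.01), beside NF-kB and cytokines, and for 2 lists with 1 of the values near 0 (integrins and focal adhesion, hypoxia and glycolysis).

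Each set was then compared with scramble. In ARF-1 the largest rises by normalized difference included SNORD13 (2.68 ± 0.09) and IL24 (2.32 ± 0.11), and 2 genes that no scramble array detected, ZNF467 (at least 4.56-fold higher) and the tubulin TUBB1 (at least 3.65-fold higher), and the largest falls CCL2 (at least 3.44-fold lower), ID3 (-1.93 ± 0.10) and RRS1 and GRWD1, which serve ribosome assembly (-1.62 ± 0.09 and -1.61 ± 0.10). In ARF-2 SNORD13 rose by 2.94 ± 0.09, IL24 by 2.64 ± 0.11 and IL11 by 2.27 ± 0.11, MAGEB2 was at least 4.90-fold higher and CCL2 at least 3.31-fold lower, and UCA1 fell by 2.13 ± 0.14, RRS1 by 1.80 ± 0.09 and PAGE5 by 1.63 ± 0.14. In ARF-4 the cystatin CST1 fell most (-3.08 ± 0.08, 8.46-fold), then AGR2 (-2.44 ± 0.10; a second probe read -0.18, adjusted p = 0.463) and PRSS3 (-2.00 ± 0.12), with CCL2 at least 3.45-fold lower. SNORD13 rose by 2.10 ± 0.09, IL24 by 1.93 ± 0.11 and IL11 by 1.91 ± 0.11 there, and MAGEB2 was at least 3.59-fold higher. Adjusted p for these 24 changes was at most 9.4e-06. ARF-1 had 5741 probes past the threshold (2893 higher, 2848 lower), ARF-2 5452 (2718 and 2734) and ARF-4 1845 (951 and 894). Median scaling gave 3071, 3180 and 662, with 37.5%, 29.1% and 32.9% of them higher, against 50.4%, 49.9% and 51.5% here. The bounds hold under the background correction used. Without it ZNF467 and TUBB1 read 1.01 and 0.94 in ARF-1, IL24 1.32, 1.56 and 1.04 and CCL2 -0.90, -0.87 and -0.89 in ARF-1, ARF-2 and ARF-4, MAGEB2 1.05 in ARF-2 and 0.79 in ARF-4, UCA1 and PAGE5 -1.14 and -0.72 in ARF-2, and AGR2 -1.82 in ARF-4. ARF-4 had 1183, 1146 and 1118 without scramble replicate 1, 2 and 3 and 1210 without ARF-4 replicate 2.

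ATF4 targets were higher and G2 and mitosis genes lower in each set. The medians of ATF4 targets were 0.51, 0.25 and 0.21 in ARF-1, ARF-2 and ARF-4, with adjusted p = 0.00755, 0.0401 and 0.0185 with an estimated correlation; those of G2 and mitosis were -0.25, -0.25 and -0.19, with adjusted p = 0.0115, 0.0197 and 0.0185 with an estimated correlation. E2F and S phase genes fell in ARF-1, where 22 of 42 fell and 1 rose (median -0.26; adjusted p = 0.0307 with an estimated correlation). In ARF-4 the hypoxia and glycolysis list was lower, with 15 of 32 falls and 0 rises (median -0.36; adjusted p = 0.0108 with an estimated correlation). Mesenchymal markers (2 rose, 6 fell; median -0.19), integrins and focal adhesion (1 rose, 8 fell; median -0.16) and the 4 basal markers (0 rose, 3 fell; median -0.52) were also lower in ARF-4, and oxidative phosphorylation genes (3 rose, 0 fell; median 0.10) higher, with adjusted p = 0.0198, 0.0198, 0.0231 and 0.0231 with an estimated correlation. Under median scaling none of these calls held with the estimated correlation; with the preset correlation all held there except oxidative phosphorylation (adjusted p = 0.211), whose call with the estimated correlation was also lost under cyclic loess. Further calls with the preset correlation were lost with the estimated one: in ARF-1 immediate early genes (adjusted p = 0.253 with an estimated correlation) and hypoxia and glycolysis (0.190), in ARF-2 E2F and S phase, immediate early genes and the endothelial and adipocyte markers (0.128 each), and in ARF-4 epithelial markers (0.0944), E2F and S phase (0.194), interferon-stimulated genes (0.0527) and luminal markers (0.0927).

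**Figure D4:**
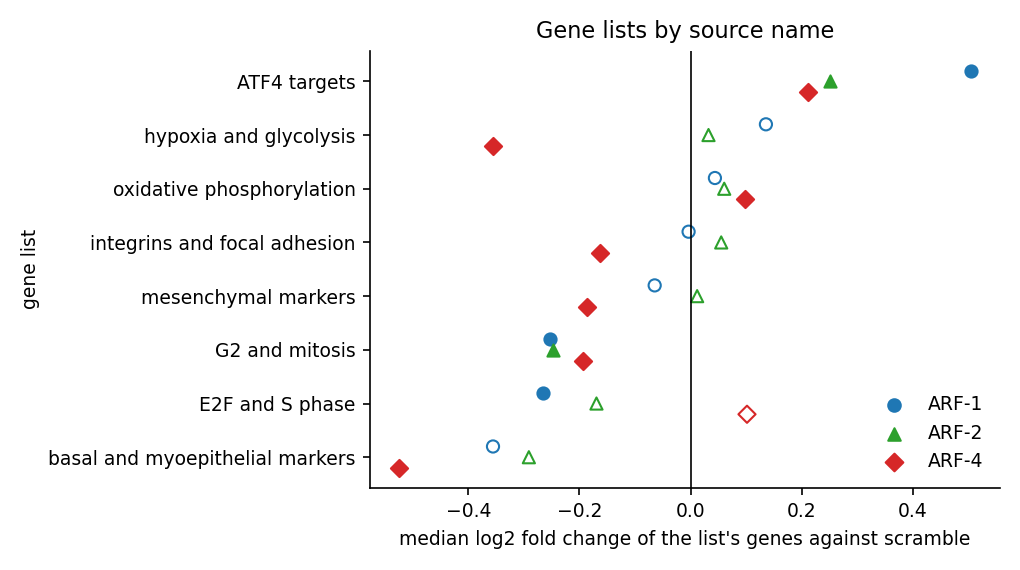
Median log2 fold change against scramble (horizontal axis) of the genes of each list (vertical axis), for the 8 lists past adjusted p of 0.05 with an estimated correlation in at least 1 set; filled symbols passed it in that set and open symbols did not. Hypoxia and glycolysis genes had a median of -0.36 in ARF-4 and 0.14 in ARF-1.

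The 3 sets differed from each other in 4401 probes of 2903 genes by the F-test, and ARF-4 stood apart. It differed from ARF-1 in 4353 probes (2210 higher, 2143 lower) and from ARF-2 in 4277 (2143 and 2134), while ARF-2 and ARF-1 differed in 14 (10 and 4). ABCA1, which exports cholesterol, and NDRG1, a gene induced by hypoxia, changed in opposite directions: ABCA1 rose by 1.59 ± 0.11 in ARF-1 and in ARF-2 as well (adjusted p = 3.3e-06), and fell by 1.00 ± 0.11 in ARF-4. NDRG1 rose by 1.34 in ARF-1 and 1.12 in ARF-2 and fell by 1.11 in ARF-4. LAIR2 rose by 1.61 in ARF-1 and 1.68 in ARF-2 and fell by 0.43 in ARF-4. CST1 and its close relative CST4, which a probe might not tell apart, read -3.08 and -1.91 in ARF-4, against -0.64 and 0.25 in ARF-1. TUBB1 was lower in ARF-2 than in ARF-1 (-1.83 ± 0.12; adjusted p = 3.7e-05), and ARF-4 lay at least 3.70-fold below ARF-1. As groups, E2F and S phase genes were higher in ARF-4 than in ARF-1 (25 of 42 higher, 0 lower; median 0.37; adjusted p = 0.00476 with an estimated correlation) and hypoxia and glycolysis genes lower (18 of 32 lower, 2 higher; median -0.39; adjusted p = 0.00476 with an estimated correlation). Immediate early genes were lower too (12 of 27 lower, 0 higher; adjusted p = 0.0324 with an estimated correlation). These 3 calls were lost under median scaling with the estimated correlation (adjusted p up to 0.935) and held with the preset one. F-test adjusted p for the 6 genes named first was at most 4.0e-07. Without background correction ARF-4 minus ARF-1 was -0.99 for TUBB1 and -1.98 for ABCA1, and ARF-4 minus ARF-2 was -1.12 for LAIR2, against -2.12 here. The F-test count was 1813 under median scaling, where the differences from ARF-4 numbered 1707 and 1655, and the ARF-2 to ARF-1 count moved between 1 and 111 over the settings.

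Against scramble, 902 probes of 564 genes changed in the same direction in all 3 sets, 538 higher and 364 lower. Independent lists of the same sizes would share 15.2 higher and 14.1 lower. In 100 simulations of unchanged groups against shared controls, 0 probes did. That outcome was nearly fixed in advance, because unchanged groups yield hardly any calls in a set. The figures for independent lists leave out the shared controls. How far lists of these sizes would overlap through shared controls alone is thus not known. Those simulations drew each probe independently with the spread within sets and held no shift of the scramble cultures. They therefore cannot tell the 902 probes from the result of such a shift. Across probes, log2 fold changes correlated at 0.88 between ARF-1 and ARF-2, 0.51 between ARF-1 and ARF-4 and 0.49 between ARF-2 and ARF-4, against 0.50 (0.48 to 0.52) for simulated unchanged groups. The covariances were 0.127, 0.0538 and 0.0509, against 0.0132 simulated. The 3 scramble arrays cannot be split with 2 in each part, so some of the excess may come from the shared controls. Among the 20 largest changes, ALOX5AP (F-test adjusted p = 0.288) and COX7B2 (0.589) did not pass the F-test among sets, and CCL2, undetected in all 3 sets, could not be compared between them. The shared count was 579 without scramble replicate 2 and 579 without scramble replicate 3, and 299 under median scaling, with 39.8% higher against 59.6% here.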

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

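The F-test and the comparisons of probes between sets were planned. The list differences between sets and the fit with array brightness were added after the data were seen. List tests of each set against scramble were not planned either. Of the tests of explanations, those of normalization, exchanged labels, other transcripts, scramble-treated cells, growth conditions and interferon were chosen after the result was seen. No array lay far from the other 8 labelled ARF1 siRNA in any of the 82 values examined. Chance would pick out 4.1 only if these arrays did not fall into sets. Differences between the sets widen the spread among the arrays, which makes an outlying array hard to flag. The lack of flags therefore does not show that no array was unusual within its set. The probe counts, genes and lists of the next 2 paragraphs were picked out by a difference between the sets of arrays.

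The sets differed in 4401 probes by the F-test, ARF-2 from ARF-1 in 14, ARF-4 from ARF-1 in 4353 and ARF-4 from ARF-2 in 4277. Of the 79 genes named in the text, 45 passed the F-test. The adjusted p was 7.58e-09 for CST1, 1.50e-07 for ABCA1, 2.32e-07 for NDRG1, 3.35e-07 for CST4, 3.97e-07 for TUBB1 and LAIR2, 1.10e-06 for RRS1, 1.40e-06 for ZNF467, 7.55e-06 for AGR2, 1.13e-05 for GRWD1, 1.20e-05 for ID3, 4.46e-05 for INSIG1 and 6.66e-05 for GABARAPL1. It was 1.26e-04 for SNORD13, 1.45e-04 for UCA1, 3.81e-04 for PRSS3, 7.92e-04 for CDH11, 8.08e-04 for KDELR3 and PAGE5, 0.00110 for NNMT, 0.00129 for MDK, 0.00130 for PPARG, 0.00183 for IL24 and COL6A1, 0.00344 for HSP90B1, 0.00380 for PHGDH, 0.00403 for FOXQ1, 0.00612 for SNAI2, 0.00619 for PSAT1, 0.00695 for MAGEB2, 0.00893 for KLF4 and 0.00927 for TRIML2. It was 0.0108 for PDLIM7, 0.0123 for CCND2, 0.0130 for RELB, 0.0160 for WIPI1, 0.0184 for CCND1, 0.0220 for MKI67, 0.0311 for ARF5, 0.0313 for SPDEF, 0.0332 for CDC25B, 0.0380 for IL11, 0.0414 for HYOU1, 0.0441 for EPCAM and 0.0490 for BIRC5.

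Among gene lists, with the preset correlation, ARF-4 was lower than ARF-1 in ATF4 targets (adjusted p = 1.52e-04), mesenchymal markers (0.00417), integrins and focal adhesion (0.00299), G1 regulators (0.0382), immediate early genes (6.30e-05), hypoxia and glycolysis (3.55e-09) and endothelial and adipocyte markers (0.0382), and higher in E2F and S phase (1.64e-10) and heat shock and proteasome (0.00602). ARF-4 was lower than ARF-2 in mesenchymal markers (0.00183), integrins and focal adhesion (0.00113), interferon-stimulated genes (0.00505), NF-kB and cytokines (0.00191), immediate early genes (3.48e-06), lysosome and autophagy (0.0323), hypoxia and glycolysis (1.15e-06) and endothelial and adipocyte markers (0.0189), and higher in E2F and S phase (4.41e-07) and heat shock and proteasome (0.00505). ARF-2 was lower than ARF-1 in ATF4 targets (4.73e-10) and hypoxia and glycolysis (0.00158), and higher in E2F and S phase (0.00313), interferon-stimulated genes (3.30e-07) and NF-kB and cytokines (4.73e-10). With an estimated correlation the differences of G1 regulators (0.0863), of endothelial and adipocyte markers (0.0995 and 0.0760), of NF-kB (0.0760) and lysosome (0.130) between ARF-4 and ARF-2, and of E2F (0.0939) and hypoxia (0.0590) between ARF-2 and ARF-1 were lost.

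The first pattern weighed is that ARF1 was not shown to be lower on the arrays labelled ARF1 siRNA. Normalization did not hide a large fall of the brightest probe, since the lowest difference over 5 other background and normalization settings was 0.0171. Exchanged labels are not settled: the brightest probe spanned only 0.282 on the log2 scale over all 12 arrays, so no array held a large fall. That argues against exchanged labels only if the siRNA lowered ARF1 and the probe reads ARF1 alone. A second transcript bound by the probes stays open: 0 of the 3 probes were lower past the threshold, which does not say what each binds. A recovery of the transcript before harvest, or an siRNA that did not act, was not tested.

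The second pattern is that the ARF-4 arrays lay apart from ARF-1 and ARF-2. Array brightness is argued against, since 4276 probes passed the F-test with the log2 mean signal as a covariate, against 4401 without. Whether the ARF-4 arrays held scramble-treated cells of another culture stays open: 1845 probes differed from scramble, but the spread within a set may be technical, so a change of culture alone might give such a count. Growth conditions of the cultures may contribute: the median of the hypoxia and glycolysis genes was -0.39 in ARF-4 against ARF-1, but culture and source name cannot be told apart because each set may be its own culture. A biological difference between the sets stays untested, since the labels do not say what the numbers mean.

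The third pattern is the changes against scramble shared by the 3 sets. A shift of the 3 scramble cultures would move all sets alike, and 28.6% of the shared probes (258 of 902) passed the F-test among the sets, against 19.8% of all probes. A shift alone was predicted to leave the share no higher than that of all probes. The share lay above that, but below the limit set beforehand for counting against a shift. The test therefore does not decide, and a shift of the controls stays open. A stronger interferon response to the ARF1 siRNA stays open too: over the 9 arrays 7 interferon-stimulated genes fell and 1 rose, but the list was not called (adjusted p = 0.515), and by set 5 rose and 9 fell in ARF-1, 9 rose and 7 fell in ARF-2, and 1 rose and 8 fell in ARF-4, where the list was lower (adjusted p = 0.0160, and 0.0527 with an estimated correlation).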

How the results depend on the processing

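The fits without the ARF-4 arrays and with array brightness as a covariate (4276 probes past the F-test, against 4401) were chosen after the data were seen. For the 9 arrays against scramble the 2423 probes became 5638 with array weights, 5267 with 4 group means, 551 with the source name as a random block and 6478 without the ARF-4 arrays. The 998 probes of at least 1.5-fold became 274 without background correction, 417 with normexp, 279 with the authors' value table, 1673 with array weights, 486 with the random block and 2264 without the ARF-4 arrays. Median scaling gave 3071 for ARF-1, 3180 for ARF-2, 662 for ARF-4, 4 for ARF-2 against ARF-1, 1707 for ARF-4 against ARF-1, 1655 for ARF-4 against ARF-2, 1813 for the F-test and 299 for probes changed in all 3 sets. For ARF-4, 2996 passed without background correction, 2995 with the value table, 2817 with a trended and robust prior and 1104 on the 6 arrays alone. The 14 probes between ARF-2 and ARF-1 became 111 without background correction, 54 with normexp, 9 with cyclic loess, 109 with the value table, 48 with the strict filter, 72 with the trended prior and 3 with the replicate block. Probes changed in all 3 sets numbered 1492 without background correction, 1490 with the value table and 1377 with the trended prior. The cause was not tested.

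Leaving out 1 array gave 844 to 3029 probes for the 9 arrays (974, 844 and 865 without scramble replicate 1, 2 and 3), 628 to 1289 at 1.5-fold (628 and 642 without scramble replicate 2 and 3), 4570 to 5745 for ARF-1, 4215 to 5442 for ARF-2 and 1118 to 1785 for ARF-4 (1183, 1146 and 1118 without scramble replicate 1, 2 and 3, and 1210 without ARF-4 replicate 2). The ARF-2 to ARF-1 count was 1 to 10: 1 without replicate 1 or 2 of either set, 3 without ARF-1 replicate 3, 5 without scramble replicate 3, 7 without scramble replicate 1 or 2 or ARF-4 replicate 3, 8 without ARF-2 replicate 3 or ARF-4 replicate 1. ARF-4 differed from ARF-1 in 3378 to 4305 probes and from ARF-2 in 3353 to 4195, the F-test gave 3135 to 4181, and 579 to 830 changed in all 3 sets (579 without scramble replicate 2 and 579 without 3). The ARF1 difference was 0.11 to 0.17, and the dimmest probe (ILMN_1661458) alone read -0.18.

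Of the 2 lists called, 0 passed with an estimated correlation (adjusted p = 0.612 for ATF4 targets and 0.302 for G2 and mitosis), 7 lists passed by fry and 4 without the ARF-4 arrays. Leaving out 1 array kept 2 lists. Named genes were refitted under 18 settings: 5 of background or normalization, the replicate block and each array left out. Of 139 called comparisons, 66 passed under all 18, 73 lost the threshold under at least 1, and 0 values reversed; array weights, the random block, 4 group means, the filters, the trended prior and the fit without ARF-4 were not run on them. Background correction sets the size of change of dim genes. Whether the replicate numbers pair the arrays is not settled: correlations over the 18 pairs with 1 number ranged from -0.022 to 0.037, while 8 of 12 arrays correlated best with an array of their own number.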

Other observations

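The ribosome biogenesis and structural RNA lists, and the tests of both hypotheses below, were chosen after the result was seen; the splits of the arrays were planned. Nucleolar genes such as RRS1 and GRWD1 were among the largest falls of ARF-1 and ARF-2, and the hypothesis was that ribosome biogenesis genes fell as a group there and not in ARF-4. Of 50 genes in a list without the genes seen falling, 29 fell and 0 rose in ARF-1 (median -0.43; adjusted p = 1.70e-04 with an estimated correlation) and 31 fell and 0 rose in ARF-2 (median -0.44; adjusted p = 6.72e-05 with an estimated correlation). In ARF-4, 1 rose and 2 fell (adjusted p = 0.632 with an estimated correlation). The difference itself, ARF-4 minus ARF-1, had a median of 0.449 (28 higher, 0 lower; adjusted p = 5.60e-05 with an estimated correlation), and ARF-4 minus ARF-2 a median of 0.49. The calls with an estimated correlation were lost under median scaling (adjusted p = 0.367 in ARF-1, 0.257 in ARF-2 and 0.236 for ARF-4 minus ARF-1), while those with the preset correlation held. The list was drawn up from and tested on the same arrays, and its genes move together (estimated correlation 0.513 in the fit of the 9 arrays against scramble). Leaving out the genes seen falling therefore does not make it an independent test, and the result only describes these arrays. In ARF-4 GRWD1 itself read -0.38 (adjusted p = 0.0322) and RRS1 -0.15 (adjusted p = 0.388). Over the 9 arrays the median was -0.29 (0 rose, 5 fell; adjusted p = 0.484 with an estimated correlation).

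Of 165 structural and small non-coding RNAs, 9 rose and 39 fell in ARF-1 (adjusted p = 0.00348 with an estimated correlation), 14 rose and 40 fell in ARF-2 (0.00357), and 26 rose and 5 fell in ARF-4 (0.00939). Under median scaling these calls were lost (0.616, 0.675 and 0.83). Over the 9 arrays the list was not called (adjusted p = 0.236).

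A second hypothesis was that the number in a source name gives the ARF family member targeted. ARF4 on the ARF-4 arrays differed from scramble by 0.169 (95% confidence interval -0.03 to 0.37; adjusted p = 0.308), which argues against a lower ARF4 transcript there and says nothing of its protein.

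For the 9 arrays against scramble, 1 of 100 splits drawn from the 220 possible, the real one, gave as many as 2423 probes, and the highest other gave 1. The same held for the 998 probes of at least 1.5-fold (highest other 1), so both counts were rare among splits of single arrays. Splits that mix arrays of different sets count the difference between sets as spread, which lowers their counts. Arrays group by set, however, and whole sets can be exchanged in only 4 ways, so chance between sets is not excluded. For the lists, 57 of the 100 splits gave as many as the real 2 and the highest other gave 10, so chance is not excluded, and the larger counts point to a structure of the arrays by set. With each set in turn as the 3 controls, 1 probe was called for ARF-1, 1 for ARF-2 and 688 for ARF-4, a split that was not among those drawn. For the F-test, 1 of 100 splits, the real one, reached 4401, and the highest other, 3882, came near it. For probes changed in all 3 sets 1 of 100, again the real one, reached 902 (highest other 380). Both counts were thus rare among splits of single arrays, which does not exclude chance between sets. For 3 arrays against 3 the 10 splits are too few for a share under 0.05: the real counts were 5741 for ARF-1, 5452 for ARF-2, 1845 for ARF-4, 14 for ARF-2 against ARF-1, 4353 for ARF-4 against ARF-1 and 4277 for ARF-4 against ARF-2, and the highest other was 0 in each.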
